A study of Mus musculus with 8 samples.

How the data were processed

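The series holds 8 single-channel arrays (Affymetrix mouse gene array, MoGene 2.0 ST) in 4 groups of 2: DMSO, 100 nM glucagon, 2 µM GW4064, and both agents, each for 6 h. Per the labels' protocols, primary hepatocytes of male C57BL/6J mice were cultured in medium that held 100 nM dexamethasone, each experiment used the pooled cells of 3 mice, 2 technical replicates were pooled per sample, and 300 ng of RNA entered labelling. The 2 samples of a group came from 2 separate experiments, so the replicates are separate cell pools. The log2 signal values were used as deposited by the authors, who processed the arrays in GeneSpring per the labels. The version, background correction, summarisation and normalization are not given in the sources used here, and that the values are on a log2 scale was read from their range. Array medians lay between 3.42 and 3.57. No measured column was left unused. Pairwise correlations over the 13845 tested genes were 0.976 to 0.997 among 7 arrays. Between these and the GW4064 array of experiment 2 they were 0.975 to 0.985.

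The table has 41345 probe sets. The platform annotation gave 1 gene symbol for 23521, several for 1814 and none for 16010, and only those with 1 symbol were tested as genes. Symbols were compared with current RefSeq symbols by gene identifier: 23328 were found, 193 were not, and 0 changed. A probe set was kept when its value exceeded the 40th percentile of its array on at least 2 arrays, which 27338 probe sets did, 14639 of them with 1 symbol. For the 615 genes with several such probe sets, the one with the highest mean was used, which left 13845 genes. No coordinates are given, because no genome build is named in the sources used here. The precision is limited by the number of arrays.

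Differences between groups were tested with limma 3.58.1 in R 4.3.3: a linear model with 1 mean per group over all 8 arrays (4 residual degrees of freedom, 3.06 prior degrees of freedom), contrasts, and empirical Bayes moderation with default settings. The 6 contrasts were glucagon against DMSO, GW4064 against DMSO, both against DMSO, both against glucagon, both against GW4064, and the interaction on the log2 scale. P-values are two-sided and were adjusted by Benjamini and Hochberg over all genes within each contrast, and a gene was said to rise or fall at an adjusted p below 0.05. The tests, lists, naming rule and alternatives were chosen before the data were examined, except those said in the text to have been chosen later. Values printed for single arrays are log2 signals, and SD and SE refer to n = 2 per group.

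The labels give each experiment its own pool of cells that was divided over the 4 treatments, so arrays of the same experiment are paired. Deviations from the group means correlated within an experiment at r = 0.350 to 0.620 for the 6 pairs of groups. The model without the experiment had been chosen as the main one, and a model with the experiment as a block (3 residual degrees of freedom) was fitted beside it. Blocked values are printed where they change a call or move a count by over 1.5 times.

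The 29 gene lists covered liver metabolism, cyclic AMP and FXR responses, stress, transcription factors and markers of hepatocytes and the other liver cell types. They were tested with camera at a preset correlation of 0.01 between genes, for lists with at least 3 measured genes, with adjustment over the 174 tests of 29 lists and 6 contrasts. Of these, 26 were called, 23 up and 3 down, and 0 held with an estimated correlation. With the block 29 were called, 24 of them the same. The rotation test fry, which asks whether a list's genes move one way and does not compare them with other genes, called 6. Genes were named by a fixed rule: per contrast, the 10 largest rises and falls past the threshold with the same sign in both experiments, or the 5 smallest p-values where none passed; up to 4 members of each list with the smallest p; and a fixed panel of 17 genes, 1 of which is not reported here. Genes outside the rule are said to be so where they are named. Predicted genes were to be counted and not named, and 0 were among the calls.

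Correlations between effects were computed across genes. For effects that share the DMSO arrays, 100 sets of unchanged groups were simulated with the blocked residual variance of each gene. The steps were tested on simulated data for glucagon against DMSO, with 13845 genes of which 200 were changed, in 20 draws. Without the block, 1.64% of genes changed 1.5-fold, 40.7% of those changed 2-fold and 92.3% of those changed 4-fold were called, with 4 false calls among 1790. With the block the shares were 27.0%, 91.6% and 99.8%, with 191 false calls among 3152. A list of 20 genes shifted by 0.5 had an unadjusted camera p below 0.05 in 20 of 20 draws, and an unshifted one in 0. The simulated genes were drawn independently of each other, so these draws do not test the preset correlation between genes.

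Alternatives were the experiment as a block or as a random effect, only the groups compared, quantile normalization or median centring of the deposited values, no filter or a filter at the 60th percentile, the mean of a gene's probe sets, all probe sets without collapsing, eBayes with trend or robust, an added fold of at least 1.5, and leaving out each array in turn. Leaving out the GW4064 array of experiment 2 together with the block was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.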

Results

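Primary hepatocytes from male C57BL/6J mice were treated for 6 h with DMSO (the solvent control), with 100 nM glucagon, with 2 µM GW4064, or with glucagon and GW4064 together. Glucagon is the fasting hormone that raises cyclic AMP in hepatocytes, and GW4064 is a synthetic agonist of the farnesoid X receptor (FXR, gene Nr1h4), the nuclear receptor for bile acids. Gene expression was measured on 8 arrays, 2 per treatment, and the number of arrays limits the precision of every value. Each array came from 1 of 2 separate experiments, each on cells pooled from 3 mice, so n = 2 in every group. Differences are given on the log2 scale with limma's standard error (SE). Among the 13845 genes tested, the first principal component (43.1% of the variance) placed each glucagon-treated array above the matching array without glucagon of the same experiment, and each array of experiment 2 above its counterpart of experiment 1. The second component, with 31.1%, set 1 array apart: the GW4064 array of experiment 2 lay at 40.2, and the other 7 arrays lay between -14.8 and 5.42. On that array olfactory and vomeronasal receptor genes, a set with low signal here, had a median signal of 3.25, against 2.95 to 2.98 on the other 7. That array enters the GW4064 group below.

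**Figure D1:**
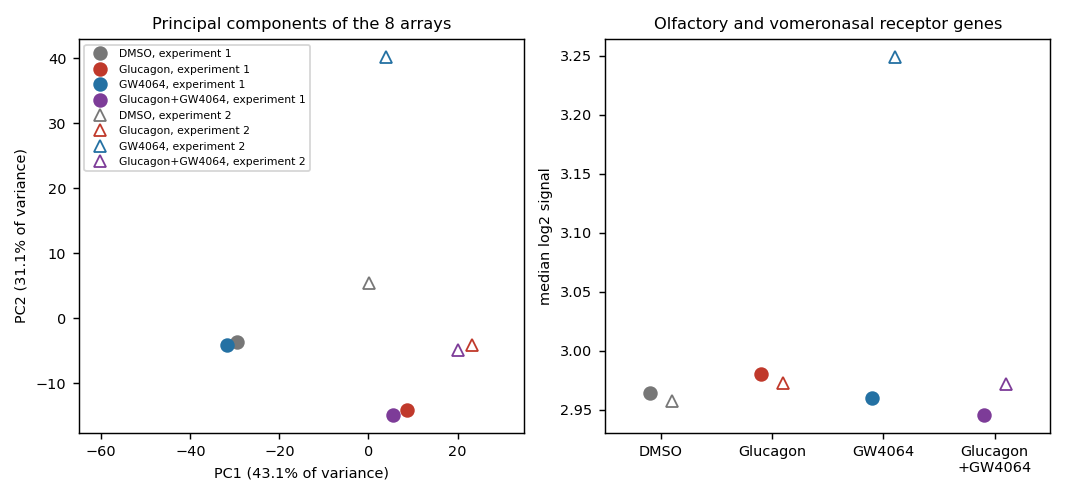
Left, the 8 arrays by the first and second principal components of the tested genes, with the share of variance on each axis; right, the median log2 signal of olfactory and vomeronasal receptor genes on each array, by treatment. Filled circles are experiment 1 and open triangles experiment 2; the GW4064 array of experiment 2 stands at 40.2 on the second component and at 3.25 in receptor signal, and the other 7 arrays stand at or below 5.42 and 2.98.

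The first comparison asked which transcripts glucagon moved in the absence of the FXR agonist. Pck1, the cytosolic phosphoenolpyruvate carboxykinase that opens gluconeogenesis, rose most (probe set 17380222; log2 difference 5.26, SE 0.39, n = 2, limma adjusted p = 0.00541; 0.0607 with only the groups compared). G6pc, the glucose-6-phosphatase that releases free glucose, rose 17.2-fold (probe set 17256707; log2 difference 4.11, SE 0.21, adjusted p = 0.0014), from a mean signal of 5.98 ± 0.07 (SD, n = 2) with DMSO to 10.09 ± 0.42 with glucagon. The orphan nuclear receptors Nr4a3 and Nr4a1, early cyclic AMP targets, rose by 4.13 (SE 0.26) and 1.85 (SE 0.12). The mean signal of Nr4a3 with DMSO was 3.16, at the filter level of 3.13 to 3.14 on those arrays, so the size of its rise here and in the comparisons below is a lower limit. Slc25a15, the ornithine carrier of the urea cycle, rose by 2.98 (probe set 17508036; SE 0.13, adjusted p = 0.00093), Slc25a22, a glutamate carrier, by 2.01 (SE 0.13), and Aass, the entry enzyme of lysine breakdown, by 2.79 (SE 0.24). In all, 15 genes rose and 1 fell. The fall was in Eda2r, a receptor of the tumour necrosis factor family, which fell by 1.18 (SE 0.13, adjusted p = 0.0412). Eda2r did not pass with quantile normalization (adjusted p = 0.0647), with only the groups compared (0.111), over all probe sets, or without any 1 of the DMSO, glucagon or combined-treatment arrays.

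The remaining genes among the 10 largest rises were Palmd (2.17), Pmvk (1.90), which phosphorylates mevalonate phosphate in cholesterol synthesis, and Tpbgl (1.89). The other 5 rises were in Ackr3, an atypical chemokine receptor (1.82), Irs2, an adaptor of the insulin receptor (1.79), Got1, the cytosolic aspartate aminotransferase (1.44), the fumarase gene Fh1 (1.31) and Shld2 (1.11); Ackr3, Fh1 and Shld2 lie outside the naming rule and were named after their values were seen. All 16 genes had the same sign in both experiments. Pck1, for example, differed by 5.79 in experiment 1 and 4.73 in experiment 2, and Slc25a15 by 2.92 and 3.03. Alb, the serum albumin gene, differed by -0.00 (SE 0.12), but its signal of 13.0 lay near the top of the range, the lowest of the array maxima being 13.2.

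With the experiment as a block, which takes out the difference between the cell pools, 128 genes passed, 89 up and 39 down, the 16 among them. With the block and without the doubted GW4064 array, 204 were up and 234 down, so the excess of rises was not kept there. Genes that passed with the block over all 8 arrays but not without it included Ppargc1a, the coactivator of gluconeogenic and mitochondrial genes (3.16, adjusted p = 0.062 without the block and 0.000774 with it). Its signal on the DMSO array of experiment 1 was at the filter level, so the sizes of its rises with glucagon here and below are lower limits. Cpt1a, the gate of fatty acid entry into mitochondria (1.88, 0.0615 and 0.00318), was another. Further ones were the transporters Slc7a2 for arginine and lysine (2.44, 0.062 and 0.0256), Slco1a4 (1.84, 0.0531 and 0.00366) and Slco2b1 (1.14, 0.0857 and 0.037), and the transsulfuration enzyme Cbs (1.22, 0.0857 and 0.037). Among genes with lower values, Socs2, a suppressor of growth hormone signalling, differed by -2.31 (0.188 and 0.00796), and Osgin1 by -1.90 (0.342 and 0.0328). The count without the block rested on single arrays: it was 2 without the glucagon array of experiment 1, 3 without that of experiment 2, 5 without the DMSO array of experiment 1, 8 without either array of the combined treatment, and 27 without either GW4064 array.

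**Figure D2:**
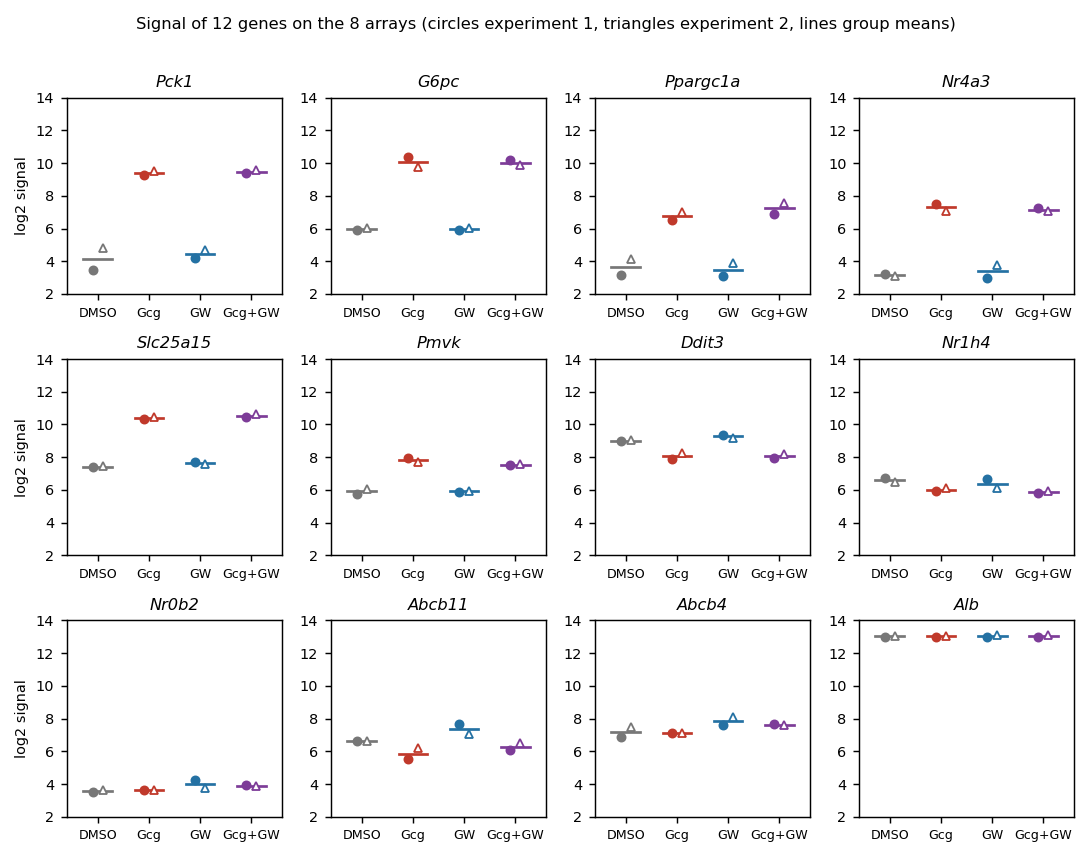
Log2 signal (vertical axes) of 12 genes on the 8 arrays by treatment (Gcg, glucagon; GW, GW4064); filled circles are experiment 1, open triangles experiment 2, and lines the mean of 2 arrays. Pck1, G6pc, Ppargc1a, Nr4a3, Slc25a15 and Pmvk have their 4 glucagon-treated arrays above their 4 others, and the albumin gene Alb lies near the top of the signal range.

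Of the 29 gene lists fixed before the data were examined, 7 had higher values with glucagon than the other genes and 1 had lower values by limma's camera test with a preset correlation. None of the 8 calls held with an estimated correlation between genes, as the p-values beside each list show. In the gluconeogenesis list, 3 of 17 measured members rose over all genes (Pck1, G6pc and Got1), 0 fell, and 4 rose adjusted over the list alone, the last being the alanine aminotransferase Gpt2 (0.89, SE 0.12, adjusted p = 0.062 without and 0.0263 with the block); with the block 5 rose. Its median difference was 0.29 (adjusted p = 1.52e-08, and adjusted p = 0.358 with an estimated correlation). Fbp1, the gluconeogenic fructose bisphosphatase, differed by 0.36 (SE 0.34) and did not pass. In the list of cyclic AMP response genes (PKA/CREB response), Nr4a3, Nr4a1 and Irs2 rose of 26 measured, with 10 up and 2 down adjusted over the list alone, and 6 up with the block. The 2 down were Junb (-0.82) and Klf9 (-0.53), named after their values were seen. The list's median was 0.16 (adjusted p = 1.12e-05, and adjusted p = 0.383 with an estimated correlation). Crem, whose short product represses cyclic AMP targets, differed by 0.25 (SE 0.14).

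The list of cholesterol synthesis had the largest median of the 29, 0.57, with 17 of 18 members positive (adjusted p = 2.45e-13, and adjusted p = 0.383 with an estimated correlation). Pmvk rose over all genes, 9 rose adjusted over the list alone, and 2 rose with the block, the second being lanosterol synthase, Lss (0.95, blocked adjusted p = 0.0421). Hmgcs1, the cytosolic HMG-CoA synthase, differed by 0.98 (SE 0.19) and Cyp51 by 0.93 (SE 0.18). In the urea cycle and amino acid list, Aass rose of 24 measured, 6 rose adjusted over the list alone, and 7 rose with the block. The median was 0.46 (adjusted p = 3.02e-10, and adjusted p = 0.383 with an estimated correlation), and Cps1, the first enzyme of the urea cycle, differed by 0.57 (SE 0.12). The lipogenesis list had a median of 0.30 (adjusted p = 0.0175, and adjusted p = 0.383 with an estimated correlation), with 0 of 18 past the test over all genes and 1 up adjusted over the list alone. That gene, Acacb, encodes the mitochondrial acetyl-CoA carboxylase whose product restrains fatty acid oxidation (1.30, SE 0.27, blocked adjusted p = 0.0139), and the next, Insig1, encodes a brake on sterol synthesis (0.88).

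The glycolysis list had a median of 0.15 (adjusted p = 0.0192, and adjusted p = 0.93 with an estimated correlation), with 0 of 17 past the test over all genes and 1 adjusted over the list alone, Pfkfb2 (1.48, SE 0.33), a kinase and phosphatase that sets fructose 2,6-bisphosphate. Its other members included Pdk2 (0.72), which restrains pyruvate oxidation, and the glycolytic enzyme gene Pklr differed by -0.29 (SE 0.21). The list of mitochondrial respiration and biogenesis had a median of 0.10 (adjusted p = 0.00497, and adjusted p = 0.702 with an estimated correlation), 0 of 19 past the test over all genes, and Ppargc1a and Idh3a (0.81) up, 2 adjusted over the list alone. The list with lower values was that of ATF4 and the unfolded protein response, with a median of -0.28 over 21 genes (adjusted p = 0.00119, and adjusted p = 0.383 with an estimated correlation). In it 0 genes passed over all genes and 4 fell adjusted over the list alone: Ddit3, the CHOP transcription factor (-0.92, SE 0.16), Nupr1 (-0.81), Ppp1r15a (-0.77) and the chaperone Hspa5 (-0.62). With the block, 3 more lists passed with higher values: bile acid synthesis (median 0.16, adjusted p = 0.0642 without and 0.00979 with the block, 0 genes up over all genes and 1, Baat (0.83, blocked adjusted p = 0.0421), adjusted over the list alone), glycogen metabolism (0.17, 0.499 and 0.0469, but 0.0873 with the block and without the doubted array, 0 and 0 genes) and complement and coagulation (0.11, 0.202 and 0.0101, 0 and 0 genes). The smallest adjusted p among the 3 with an estimated correlation was 0.978.

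The FXR-induced list did not shift with glucagon by the test (19 genes, median -0.02, adjusted p = 0.989, 0 genes past over all genes and 0 adjusted over the list alone; with the block 0 up and 1 down, Osgin1, given above). Within it Abcb11, the bile salt export pump, differed by -0.77 (SE 0.29). The receptor gene Nr1h4, which is not in that list, differed by -0.61 (SE 0.21, adjusted p = 0.588). Foxa2 differed by 0.51, Cyp8b1, the sterol 12-hydroxylase of bile acid synthesis, by 0.17 (its group means of 3.22 to 3.41 lay near the filter level, so its values in all comparisons say little), Nr0b2, the small heterodimer partner, by 0.06, and the glucagon receptor gene Gcgr by 0.05, and none passed. Bile acid and organic anion transport had a median of 0.01 (adjusted p = 0.61, 0 genes over all genes and 2 up, Slco1a4 and Slco2b1, adjusted over the list alone). Fatty acid oxidation and ketogenesis had a median of 0.05 (adjusted p = 0.499, 0 genes over all genes, and Cpt1a up and Angptl4 down adjusted over the list alone). Insulin and growth factor signalling had a median of 0.08 (adjusted p = 0.058, 1 gene up over all genes, Irs2, and 1 up and 1 down, Socs2, adjusted over the list alone). Liver transcription factors had a median of -0.00 (adjusted p = 0.499), with 0 genes over all genes and 1, Prox1 (1.07), adjusted over the list alone.

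The other lists had 0 genes past the test both over all genes and adjusted over the list alone. Their medians were 0.13 for proliferation (adjusted p = 0.438), 0.12 for lipoproteins (0.438), 0.05 for autophagy (0.81), 0.01 for the acute phase (0.789), -0.00 for xenobiotic metabolism (0.973), -0.04 for the circadian clock (0.829) and -0.08 for the NRF2 response (0.61). Markers of cell types did not shift with glucagon by the test either. Medians were 0.02 for hepatocytes (adjusted p = 0.764), 0.02 for Kupffer cells and macrophages (0.507), 0.06 for sinusoidal endothelium (0.789), -0.16 for stellate cells (0.789), -0.09 for cholangiocytes (0.335) and 0.12 for lymphocytes and neutrophils (0.475), with 0 genes past the test in each, also adjusted over the list alone. Endothelial markers had a median signal of 4.55 with DMSO and 4.19 with glucagon in experiment 1, and 3.97 and 3.77 in experiment 2. With GW4064 and the combined treatment it was 4.59 and 4.38 in experiment 1, and 3.91 and 3.76 in experiment 2. These are levels of the middle marker on each array. They can fall while the median difference of the same markers, 0.06 with glucagon, does not.

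**Figure D3:**
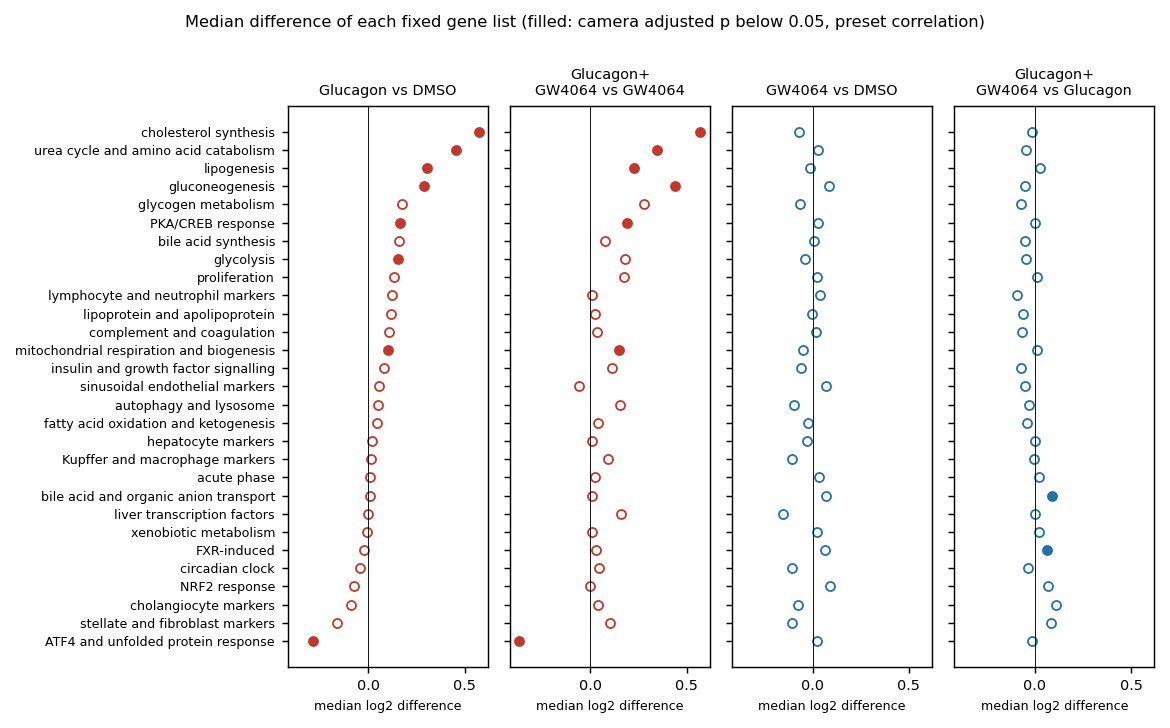
Median log2 difference (horizontal axes) of each of the 29 fixed gene lists for glucagon without and with GW4064 and for GW4064 without and with glucagon; filled points passed limma's camera test with the preset correlation at an adjusted p below 0.05, and none passed with an estimated one. Cholesterol synthesis lies farthest to the right for glucagon, at 0.57 without and 0.57 with GW4064, and ATF4 and unfolded protein response genes farthest to the left, at -0.28 and -0.37.

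The second comparison asked which transcripts GW4064 moved on its own. It rests on the GW4064 array of experiment 2, whose receptor-gene signal of 3.25 exceeded that of the other arrays. Of the 19 genes of the FXR-induced list 11 had positive values, and none passed the test. Abcb11 differed by 0.75 (SE 0.29, n = 2; 1.05 in experiment 1 and 0.44 in experiment 2), Abcb4, the phospholipid exporter of bile, by 0.69 (SE 0.23; 0.74 and 0.64), Osgin1 by 0.74 (SE 0.48; 0.66 and 0.81) and Nr0b2 by 0.42 (SE 0.17; 0.70 and 0.13), while Vldlr, the VLDL receptor gene, differed by -0.22, Cyp2b10 by -0.15 and Fetub by -0.13, these 3 named after their values were seen. Nr0b2 was dim, with a mean signal of 4.00 with GW4064, close to the level of 3.13 to 3.27 that marks the lower 40% of probes. Gluconeogenic genes had values of 0.30 for Pck1 (SE 0.39; 0.71 and -0.10), -0.00 for G6pc (SE 0.21), 0.14 for Fbp1 and -0.13 for Ppargc1a. Other panel genes had values of 0.23 for Pklr, -0.01 for Cyp8b1, -0.24 for Nr1h4, -0.24 for Gcgr, -0.22 for Foxa2, -0.03 for Crem and 0.03 for Alb.

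By limma, 0 genes passed for GW4064 against DMSO (smallest adjusted p = 0.999), and 373 had an unadjusted p under 0.05, where 692.25 would by chance. With the block 0 passed (smallest adjusted p = 0.786; 720 at an unadjusted p under 0.05), and with the block and without the doubted array 0 passed (smallest adjusted p = 0.183). The 5 genes with the smallest p were Btbd35f2 (-0.77, SE 0.13), Olfr202 (0.71, SE 0.12), Lrrc61 (-1.07, SE 0.20), the interleukin 22 receptor gene Il22ra1 (0.78, SE 0.15) and Gprc5c (0.56, SE 0.12). Without the GW4064 array of experiment 1, which leaves only the array that stood apart, 406 genes passed. None of the 29 lists passed, with or without the block. Without the doubted array, which leaves GW4064 in experiment 1 only, 3 passed without the block, all with lower values (bile acid synthesis, adjusted p = 0.0211, and complement and coagulation and hepatocyte markers, 0.0311 each), and 0 with it. Over all 8 arrays the FXR-induced list came nearest, with a median of 0.06 and a mean of 0.14 over 19 genes (adjusted p = 0.0655), and bile acid synthesis had a median of 0.01 (adjusted p = 0.951). In every list 0 genes passed over all genes and 0 adjusted over the list alone. Cyp7a1, the rate-limiting enzyme of bile acid synthesis and a gene that FXR represses, was not tested, since its highest signal on any array was 3.38 and it did not clear the filter. Slc51a (highest signal 2.91) did not clear it either, and Slc51b has no probe set of its own in the annotation used.

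The effect of GW4064 on top of glucagon uses neither the DMSO nor the GW4064 arrays in its difference. Here the 4 FXR targets named above with positive values had values of 0.43 for Abcb11 (SE 0.29; 0.56 and 0.29 in the experiments), 0.52 for Abcb4 (SE 0.23), 0.93 for Osgin1 (SE 0.48) and 0.27 for Nr0b2 (SE 0.17), and none passed. Pck1 differed by 0.09 (SE 0.39), G6pc by -0.06 (SE 0.21), Fbp1 by 0.22 and Ppargc1a by 0.46 (SE 0.42). The 5 genes with the smallest p were Mybl1, a MYB-family transcription factor (2.06, SE 0.33; 2.35 and 1.78), Acnat2 (-0.80), the pregnane X receptor gene Nr1i2 (1.16, SE 0.31), the bile acid conjugating enzyme gene Baat (-0.47, SE 0.13) and Cdnf (0.40). By limma 0 genes passed (90 at an unadjusted p under 0.05), 0 with the block (194), and 0 with the block and without the doubted array, where the smallest adjusted p was 0.0997, for Mybl1.

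The FXR-induced list had higher values with GW4064 on top of glucagon (median 0.06, mean 0.14, 12 of 19 genes positive, camera adjusted p = 0.0192, 0.0301 with the block, and adjusted p = 0.383 with an estimated correlation). Bile acid and organic anion transport also had higher values (median 0.09, 13 genes, adjusted p = 0.00635, and adjusted p = 0.383 with an estimated correlation), but with the block its adjusted p was 0.124. Its members included Abcb1a (0.94, SE 0.37) and Slco2b1 (0.43, SE 0.17). With the block, complement and coagulation had lower values (median -0.06, adjusted p = 0.319 without and 0.0307 with the block) and the NRF2 response, the defence against oxidants, higher ones (median 0.07, 0.101 and 0.0334), but without the doubted array these blocked values were 0.0527 and 0.0704; with an estimated correlation their adjusted p values were 0.995 and 0.762. In each of these 4 lists 0 genes passed over all genes and 0 adjusted over the list alone. Across genes, which are not independent replicates, the GW4064 differences without and with glucagon, taken from disjoint arrays, correlated at r = 0.0555 (Spearman's rho 0.0288; r = 0.113 within experiment 1 and 0.0472 within experiment 2).

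The combined treatment was then set against DMSO. Pck1 rose by 5.35 (SE 0.39, adjusted p = 0.00481), G6pc by 4.04 (SE 0.21), Nr4a3 by 3.98, Ppargc1a by 3.63 (SE 0.42, adjusted p = 0.0494), Slc25a15 by 3.12, Aass by 2.62, Tpbgl by 2.14, Palmd by 2.07, Mettl7b by 1.84 (adjusted p = 0.0494) and Nr4a1 by 1.81. In all 17 genes rose and 0 fell (861 at an unadjusted p under 0.05), with the block 71 rose and 31 fell, and with the block and without the doubted array 170 rose and 172 fell. Among the 17 was Slco2b1 (1.56, SE 0.17), an organic anion transporter whose other probe set gave 0.05. Values that did not pass included -0.35 for Abcb11, -0.76 for Nr1h4 (SE 0.21), 0.58 for Fbp1, 0.50 for Foxa2, 0.33 for Nr0b2, 0.29 for Crem, -0.20 for Pklr, 0.18 for Cyp8b1, 0.13 for Gcgr and 0.01 for Alb. The count was 2 without either array of the combined treatment, 6 without the DMSO array of experiment 1 and 10 without that of experiment 2, and 7 without either glucagon array.

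With the combined treatment 9 lists passed against DMSO. Gluconeogenesis (median 0.31, adjusted p = 6.28e-09), cyclic AMP response (0.26, 6.7e-07), cholesterol synthesis (0.53, 4.54e-14), urea cycle and amino acid catabolism (0.38, 8.47e-11), lipogenesis (0.14, 0.0127), glycolysis (0.18, 0.0233) and mitochondrial respiration (0.14, 0.00119) had higher values, and ATF4 and unfolded protein response genes lower ones (-0.32, 0.000533). The 9th, bile acid and organic anion transport, had a median of 0.06 (0.033, and 0.154 with the block). With an estimated correlation the adjusted p values ran from 0.358 to 0.93, so no call held. Members that rose over all genes and adjusted over the list alone were 3 and 4 for gluconeogenesis, 4 and 10 for the cyclic AMP response, 1 and 9 for cholesterol synthesis, 1 and 6 for amino acids, 1 and 2 for mitochondrial respiration, 1 and 2 for transport, 0 and 1 for lipogenesis and 0 and 0 for glycolysis, and 0 and 4 fell among ATF4 and unfolded protein response genes. The pregnane X receptor gene Nr1i2 differed by 1.83 (SE 0.31, adjusted p = 0.157).

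Glucagon in the presence of GW4064 gave a similar set of leading genes. Pck1 rose by 5.05 (SE 0.39, adjusted p = 0.00714), G6pc by 4.05 (SE 0.21), Ppargc1a by 3.76 (SE 0.42, adjusted p = 0.0358), Nr4a3 by 3.75, Slc25a15 by 2.91, Aass by 2.63, Slc7a2 by 2.55 (adjusted p = 0.0497), Tpbgl by 2.09, Palmd by 1.87 and Irs2 by 1.84. The fall was in Egr1, an immediate-early transcription factor (-1.72, SE 0.21, adjusted p = 0.0497). Egr1 did not pass with median centring (adjusted p = 0.0527), without the filter (0.0599), with the mean of probe sets (0.0508), with robust eBayes (0.0535), with only the groups compared (0.142), over all probe sets, without the GW4064 array of experiment 2 (0.139, no block) or without any 1 of the glucagon or combined-treatment arrays. In all 22 genes rose and 1 fell (1453 at an unadjusted p under 0.05), and with the block 97 rose and 50 fell, among them Ddit3 (-1.20, blocked adjusted p = 0.0262) and Osgin1 (-1.70, 0.0442). With the block and without the doubted array 88 rose and 102 fell. Values of panel genes that did not pass were -1.09 for Abcb11 (SE 0.29; adjusted p = 0.0358 with the block and without the doubted array), -0.52 for Nr1h4, -0.43 for Pklr, -0.09 for Nr0b2, -0.02 for Alb, 0.19 for Cyp8b1, 0.32 for Crem, 0.37 for Gcgr, 0.45 for Fbp1 and 0.72 for Foxa2. This comparison holds the GW4064 array that stood apart, and its count was 9 without that array, 759 without the GW4064 array of experiment 1, 2 without either array of the combined treatment and 7 without either glucagon array. Slco2b1 rose by 1.71, and its other probe set, dimmer on average, gave -0.80.

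Here 7 lists passed, and none with an estimated correlation. Higher values were found for gluconeogenesis (median 0.44, adjusted p = 6.9e-05; 3 up over all genes and 5 adjusted over the list alone), cyclic AMP response (0.19, 0.00335; 4 up, and 11 up and 2 down), cholesterol synthesis (0.57, 8.47e-11; 1 and 11 up) and amino acid catabolism (0.35, 2.84e-06; 2 and 6 up). They were also found for lipogenesis (0.23, 0.0446; 0 and 2 up) and mitochondrial respiration (0.15, 0.00336; 1 and 2 up). ATF4 and unfolded protein response genes had lower values (-0.37, 0.000781; 0 and 4 down). With an estimated correlation the adjusted p values were 0.702 for mitochondrial respiration and 0.383 for each of the other 6. Without the doubted array, mitochondrial respiration did not pass (adjusted p = 0.0607, and 0.0821 with the block), and ATF4 and unfolded protein response genes passed only with the block (0.0607 and 0.00282). Then bile acid synthesis passed with higher values (0.0132 and 0.026), complement and coagulation only without the block (0.041 and 0.396) and liver transcription factors only with it (0.0594 and 0.0447). The glycolysis list had a median of 0.18 and did not pass (adjusted p = 0.302; without the doubted array 0.0311, and 0.106 with the block).

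The interaction asked whether the glucagon effect differed with GW4064 present. Its values were -0.21 for Pck1 (SE 0.55), -0.06 for G6pc (SE 0.30), 0.59 for Ppargc1a (SE 0.60), -0.32 for Abcb11 (SE 0.41), -0.15 for Nr0b2 (SE 0.24), 0.09 for Nr1h4, 0.08 for Fbp1, 0.08 for Crem, 0.21 for Foxa2, 0.32 for Gcgr, -0.14 for Pklr, 0.03 for Cyp8b1 and -0.02 for Alb. By limma 0 genes passed (149 at an unadjusted p under 0.05), 0 with the block (332) and 0 with the block and without the doubted array, and 0 of the 29 lists passed. Without the doubted array, 2 lists passed without the block (hepatocyte markers, adjusted p = 0.0374, and sinusoidal endothelial markers, 0.0424) and 0 with it. The 5 genes with the smallest p were Lrrc61 (1.37, SE 0.28), Btbd35f2 (0.88), Defa34 (0.79), the interferon-induced Ifi204 (-1.08) and Ifit3 (1.01). A test that missed its threshold at these standard errors does not show equal effects.

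**Figure D4:**
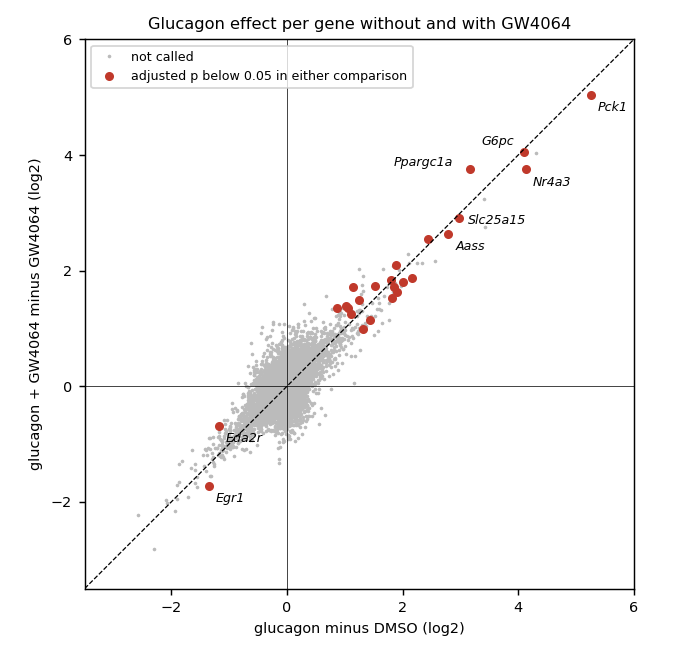
Log2 difference of each tested gene for glucagon against DMSO (horizontal axis) and for glucagon with GW4064 against GW4064 (vertical axis); red points passed limma's test in either comparison, grey points in neither, and the dashed line marks equal values. Pck1 lies at 5.26 and 5.05 and G6pc at 4.11 and 4.05, and across genes r was 0.716.

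Without and with GW4064, the glucagon differences come from disjoint arrays. Across genes they correlated at r = 0.716 (Spearman's rho 0.526; r = 0.806 within experiment 1 and 0.407 within experiment 2). Of the 15 and 22 genes that rose, 14 were shared, where independent lists would share 0.0238. With the block, 69 of 89 and 97 rises and 29 of 39 and 50 falls were shared, against 0.624 and 0.141. Both comparisons use the same estimate of each gene's spread and the same cell pools, so the lists were not independent. The expected counts are therefore a reference only and no test of the overlap. All 128 genes past the blocked test for glucagon had the same sign with GW4064 present, and their median ratio of the log2 difference with GW4064 to that without was 0.904. These genes were chosen by their difference without GW4064, so a somewhat smaller difference with it is expected from that choice alone. The difference with GW4064 also uses the array that stood apart, so the ratio does not show a damping by GW4064. Glucagon and GW4064, which share the DMSO arrays, gave differences that correlated at r = 0.0992, where simulated unchanged groups gave 0.499. The covariance was 0.00638 against a simulated 0.0133. The simulated groups held no treatment effect, and a shared control alone sets their correlation. Their noise was estimated with the doubted GW4064 array included. The lower observed values therefore do not show that the 2 agents act in opposite directions.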

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

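The blocked model without the GW4064 array of experiment 2 was the only test here chosen after the results were seen. For glucagon against DMSO, 16 genes passed; the count was 128 with the block, 59 with the experiment as a random effect (consensus correlation 0.233), 9 with only the groups compared, 8 over all probe sets, 438 with the block and without that array, and 2 to 27 when 1 array was left out (2 without the glucagon array of experiment 1, 27 without either GW4064 array). For the combined treatment against DMSO, 17 passed, and the counts in the same order were 102, 48, 9, 7, 342, and 2 to 24 (2 without either array of the combined treatment). For the combined treatment against GW4064, 23 passed, and they were 147, 75, 3, 6, 190, and 2 to 759 (2 without either array of the combined treatment, 759 without the GW4064 array of experiment 1). For GW4064 against DMSO, 0 passed under every planned setting but the leaving out of 1 array, which gave 0 to 406, with 406 without the GW4064 array of experiment 1. For GW4064 on top of glucagon and for the interaction, 0 passed under every setting run. With 1 array of a group left out, the lone remaining array is assumed to vary like the other groups. The report names each array whose loss moved these counts over 1.5 times. Comparing only 2 groups leaves fewer degrees of freedom, and testing all probe sets widens the adjustment; for the other changes the cause was not tested.

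The other settings (quantile normalization, median centring, no filter or a stricter one, the mean of probe sets, eBayes with trend or robust, and an added fold of at least 1.5) gave counts within 1.5 times the reported ones. For glucagon against DMSO, all 16 genes were kept with the block, with the random effect, under both filters and with the mean of probe sets, trend and robust eBayes; 14 were kept with quantile normalization, 15 with centring and 8 with only the groups compared. For the combined treatment against DMSO and against GW4064, all 17 and 23 were kept with the block, the random effect, the stricter filter and trend; 15 and 20 were kept with quantile normalization, with centring and without the filter, 13 and 19 with the mean of probe sets, 14 and 20 with robust eBayes, and 8 and 3 with only the groups compared. The number of gene lists called was 26. That number was 0 with an estimated correlation, 6 by fry and 29 with the block, 24 of these 29 among the 26. It was 21 to 45 with 1 array left out (45 without the DMSO array of experiment 2). No called gene, taken by its reported probe set, reversed its direction, but the other probe set of Slco2b1 gave -0.80 against GW4064. Lost calls among the named genes included, for the combined treatment against DMSO, Ppargc1a and Mettl7b without the filter, with the mean of probe sets, with robust eBayes and with only the groups compared (adjusted p up to 0.0894; Mettl7b also with median centring), and against GW4064, Slc7a2 under these and quantile normalization (up to 0.157), and Slco2b1 in both with the mean of probe sets (0.0839 and 0.263). Beyond the genes and lists given in the report, the block changed no other call among the values printed. Centring shifted the median difference of all genes for GW4064 against DMSO from -0.03 to -0.10 and for the interaction from 0.03 to 0.10. The correlation of the glucagon and GW4064 differences was 0.0992, and 0.499 in simulated groups with shared DMSO arrays. Those groups held no treatment effect, so the gap between these values has no direct reading. The random effect and robust eBayes were not run for list tests, since camera takes neither, and only the groups compared was not run for the interaction, which uses all groups.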

Other observations

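The tests of background, culture state, the share of other liver cells, the left-out array and cytoskeletal genes were chosen after the results were seen, and the tests of a GW4064 response, scaling, intensity and array number before. Genes named in this paragraph and the next were chosen for it after their values were seen; all but Oat and Hgd lie outside the naming rule, which named those 2 in other contrasts. They are single genes higher with glucagon than with DMSO in the blocked model (adjusted p without and with the block), and whether enzymes of their kind moved as a group was not tested beyond the urea cycle and amino acid list. Etnppl, a phosphoethanolamine lyase, differed by 4.31 (0.0857 and 0.000774) and by 4.03 with GW4064 present. Mat1a, the liver methionine adenosyltransferase, differed by 3.43 (0.184 and 0.00318), Oat, ornithine aminotransferase, by 2.25 (0.257 and 0.00156), and Aldh4a1, a proline breakdown enzyme, by 1.53 (0.062 and 0.00318). Hal, which opens histidine breakdown, differed by 1.84 (0.729 and 0.0384), Arg1, the last enzyme of the urea cycle, by 1.58 (0.728 and 0.00479), Hgd of tyrosine breakdown by 1.57 (0.6 and 0.0203) and Acmsd of tryptophan breakdown by 1.12 (0.64 and 0.00857). These rest on the blocked model, since none passed without it against DMSO.

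Single genes lower with glucagon in the blocked model were picked in the same way. None of them passed without the block, where the only fall was in Eda2r. Slc4a11, a membrane transporter, differed by -2.08 (adjusted p = 0.00156 with the block) and Plaur, the urokinase receptor, by -1.55 (0.0281). Osmr, the oncostatin M receptor, differed by -1.26 (0.0189) and the iron exporter Slc40a1 by -1.15 (0.0167). Il17ra differed by -1.12 (0.0367) and Iqgap1 by -1.01 (0.0392). The actin linker Msn differed by -0.95 (0.0203) and Wwtr1 (TAZ), a relative of YAP, by -0.85 (0.0296). A hypothesis that glucagon lowered YAP/TEAD targets or SRF and actin genes was tested with lists drawn up without the genes that prompted it, among 36 tests of 6 lists in 6 contrasts. The YAP/TEAD list had a median of -0.20 over 17 genes (adjusted p = 0.05652; 0.036 with the block; 1.00 with an estimated correlation) and the SRF and actin list a median of -0.21 over 17 (adjusted p = 0.1866; 0.0654 with the block). Of the 36 tests 0 passed by camera without the block and 5 with it: both lists in the combined treatment against DMSO (0.0427 each) and against GW4064 (0.0427 for YAP/TEAD and 0.036 for SRF and actin), and YAP/TEAD for glucagon. Without the GW4064 array of experiment 2, 15 passed without the block and 8 with it. Among these, with and without the block, the SRF and actin list was lower with glucagon (0.0412 without and 0.021 with the block), higher for GW4064 against DMSO (0.000795 and 0.000447) and lower in the interaction (0.00165 and 0.00138), and the YAP/TEAD list was lower with glucagon (0.0112 and 0.0145). With GW4064 these values rest on 1 array, and with an estimated correlation 0 of the 36 passed in any of these models. The other 4 lists had medians of -0.26 for MAPK feedback (adjusted p = 0.11), 0.18 for interferon-stimulated genes (0.792), 0.04 for mitochondrial carriers other than the ornithine and glutamate ones (0.405) and -0.01 for ribosomal proteins (0.97). Without the GW4064 array of experiment 2 and without the block, the MAPK, interferon and ribosomal lists also passed in some contrasts. With the block they did not. The hypothesis stays open.

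The GW4064 array of experiment 2 stood apart from the other 7. Receptor genes lay higher on it by 0.2686 than on the highest other array, and this may reflect raised background. Over all probe sets its lower quartile was 2.99, against 2.86 to 2.90 on the other arrays. Its upper quartile was 5.34, against 5.45 to 5.52. A median shift of -0.03 in 348 small RNA probe sets lay within the -0.04 to 0.05 of the other arrays. How far added background would move these probe sets depends on their signal, which was not examined. They had passed the signal filter and may be brighter than the receptor genes, so they cannot decide. The GW4064 minus DMSO difference correlated between experiments at r = 0.004228, below the limit set beforehand for a response to GW4064 as the cause. The combined treatment minus glucagon, which does not use this array, gave r = 0.0993, also below that limit. The test therefore cannot decide whether a response to GW4064 was the cause. Scaling was argued against. After quantile normalization the array's mean correlation with the others stayed below the lowest of the other 7, by -0.004548.

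The experiments differed in the genes that glucagon moves: the experiment 2 minus 1 difference on DMSO and glucagon arrays correlated with the glucagon effect on the other arrays of experiment 1 at r = 0.3516, and 728 genes differed between experiments. The glucagon difference in experiment 2 had a slope of 0.458 on that in experiment 1, with a correlation of 0.596 between them. Their SDs across genes were 0.294 in experiment 2 and 0.383 in experiment 1. Noise in these single-array differences lowers such a slope by itself, so it does not measure how much weaker the response was. A culture state that differs between the pools could account for the r of 0.3516. Intensity-dependent normalization was argued against, as r stayed at 0.35 after cyclic loess. A different share of other liver cells cannot be told apart from a culture state. Over 155 hepatocyte genes r was 0.1782 (permutation p = 0.03) and Spearman's rho 0.354. Endothelial and macrophage markers moved apart between experiments, with medians of -0.35 and 0.11 and means of -0.41 and 0.17 (permutation p of the means = 2e-05). Both permutations shuffled genes, which are not independent replicates, so these p-values measure no spread between experiments. Macrophage markers lay near the filter level (3.21 to 3.33), and a change in endothelial cells alone stays open.

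For GW4064 against DMSO no gene passed by limma (373 at an unadjusted p under 0.05). In simulated data with 2 arrays per group, 40.67% of genes changed 2-fold were called without the block and 91.6% with it. Of genes changed 1.5-fold, 1.64% and 27.0% were called, so changes of that size could be missed. The simulation shifted the glucagon group, with equal noise on all arrays and no array that stood apart. Its shares therefore need not hold for GW4064, where 0 genes passed in either model. Changes of 2-fold could be missed there too. Small changes and an array of experiment 2 that hides a response cannot be told apart: with the block and without that array, 0 genes passed for GW4064 against DMSO or on top of glucagon, and the smallest adjusted p fell from 0.786 to 0.183.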
